A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

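Polyadenylated RNA of 4 Saccharomyces cerevisiae strains was sequenced, with 1 library per strain. Per the labels, the strains were WT (DPB249), AGO1 (DPB252), DCR1 (DPB255) and AGO1DCR1 (DPB258), named after the Argonaute and Dicer proteins they carry. S. cerevisiae has neither protein of its own. The cells grew in rich liquid medium at 30 °C to log phase. RNA was extracted with hot phenol, treated with DNase I, selected on oligo-dT beads in 2 rounds and fragmented by alkaline hydrolysis. Adaptors were ligated to both ends before reverse transcription and amplification, so that reads kept the strand of the RNA. The deposited values are counts: for each distinct 30-base read sequence, the number of reads with exactly that sequence. The authors' base caller, aligner and genome build are not given in the sources used here, and the deposited sequences were not aligned.

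The libraries held 34663871 reads (WT), 34533944 (AGO1), 37844875 (DCR1) and 35203091 (AGO1DCR1). Each read was placed on genome build R64 by an exhaustive search that allowed 1 mismatch and kept the places with the fewest mismatches. The share of reads placed once was 49.5% in WT, 46.0% in AGO1, 42.6% in DCR1 and 45.9% in AGO1DCR1, and the share placed nowhere was 39.5%, 40.8%, 47.9% and 45.3%. Placing was tested on 20000 simulated reads: all reads with 0 or 1 mismatch and 0.151% of those with 2 were placed.

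A read was counted for a gene when it was placed once and both its ends lay in exons of 1 annotated gene on the sense strand. This gave 13913985 reads in WT, 13143838 in AGO1, 12346430 in DCR1 and 12327300 in AGO1DCR1. Of 5913 genes counted, 210 had no sense read in any library, and 91 Ty genes were left out of the gene counts. The annotation marked no open reading frame as dubious. Libraries were scaled by median-of-ratios factors of 1.01 (WT), 1.04 (AGO1), 0.913 (DCR1) and 1.04 (AGO1DCR1). Ratios are log2 ratios of scaled reads with 0.5 read added to each count. Each ratio has a 95% exact interval from its 2 counts (conditional binomial, Clopper-Pearson). These intervals, and the limit of 3 reads that a count of 0 allows, cover counting error only, since amplified reads are not independent molecules. A limit of 3 reads equals 2.97 scaled reads in WT, 2.87 in AGO1, 3.28 in DCR1 and 2.89 in AGO1DCR1.

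With 1 library per group there was no test across samples and no p-value. A gene was called higher or lower when it had at least 100 scaled reads in at least 1 of the libraries compared, differed at least 2-fold and had an interval that excluded a ratio of 1. In simulated counts, 50 of 50 genes were called at each of 2.5-fold, 4.0-fold and 8.0-fold, 0 of 50 at 1.5-fold and 0 of 4957 unchanged genes. The simulated counts were Poisson draws without amplification or spread between libraries. They therefore tested the rule under counting error only and give no rate of false calls in the real libraries. The spread of log2 ratios is the median absolute deviation (MAD) over genes, beside the value from simulated Poisson counts. Genes were named by a rule: the 12 largest and 12 smallest ratios for AGO1DCR1 against WT, the 5 largest and 5 smallest for each other comparison, and the 8 genes farthest above and below all other libraries in AGO1DCR1. The rule also named all marker genes, and up to 4 members, by size of ratio, of each list in the lowest or highest 1% of random lists. The value of 1 gene that this rule named is not reported here. Genes added to these, which were chosen after their values were seen, are said to be so.

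The 31 gene lists and the gene rule were fixed in advance. The lists were marker genes, ribosomal proteins, ribosome biogenesis, general stress response, heat shock factor chaperones, unfolded protein response, amino acid biosynthesis, sulfur metabolism, purine biosynthesis, glycolysis and fermentation, respiration and TCA cycle, glucose-repressed carbon use, hexose transporters, phosphate regulon, iron regulon, zinc regulon, mating type a specific, mating type alpha specific, haploid specific and pheromone response, meiosis and sporulation, histones, cell cycle, cell wall, subtelomeric families, RNA decay and surveillance, viral dsRNA host factors, translation factors, antisense regulated loci, oxidative stress, sterol and lipid synthesis, and multidrug resistance. A list's median log2 ratio was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, using members with a mean of at least 20 scaled reads. The percentile describes these libraries. ARG5,6, ADE5,7 and IMD1 were not found in the annotation and were not used.

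Ty reads, including those with several places, were summed by family when all their places lay in elements of 1 family in 1 orientation. Reads placed nowhere were also searched against Ty1 with 2 to 4 mismatches, counting those nearer to Ty1 than to any other family. Antisense reads were those placed once on the opposite strand of a gene, outside genes of that strand. Their ratios were taken over 1707 genes with at least 20 antisense reads in the AGO1 and DCR1 libraries pooled. Genes with most antisense were the top 10% by antisense to sense ratio in the AGO1 and DCR1 libraries pooled, among genes with at least 100 sense reads. Convergent neighbours were genes whose neighbour on the other strand ended within 300 bp. Reads were also searched in all frames for proteins absent from R64, counting a read when it matched 9 residues exactly, with reversed proteins as a control.

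Alternatives fixed before the data were examined were scaling by total sense reads or by TMM, read minimums of 20, 500 or none, reads of both strands, each distinct read position counted once, reads with several places shared between them, reads without mismatch, a 1.5-fold threshold, 5 reads added, Ty reads placed once, other antisense and convergent sets, a 2-fold distance for the library set apart, and the mean of WT, AGO1 and DCR1 as reference. Added after seeing the data were removal of a quadratic trend on GC content, length and expression, a 2-fold difference required in both sets of alternating 60-base blocks of each gene, and omission of the AGO1 library. Programs were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. TMM factors came from edgeR 4.0.16 in R 4.3.3.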

Results

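RNA-seq libraries were made from 4 S. cerevisiae strains: WT, a strain with Argonaute (AGO1), a strain with Dicer (DCR1) and a strain with both proteins (AGO1DCR1). The series asks how RNA interference, which needs both proteins, affects the transcriptome. Each group had 1 library, so no value below has a replicate check. The libraries held 34663871 reads in WT, 34533944 in AGO1, 37844875 in DCR1 and 35203091 in AGO1DCR1. Sense reads of genes numbered 13913985, 13143838, 12346430 and 12327300 in the same order. They started at 1344254 distinct positions in WT, 468039 in AGO1, 1284298 in DCR1 and 845549 in AGO1DCR1, so that AGO1 had 28.1 reads per position against 10.3 in WT.

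The strain labels were checked on the reads first. Reads coding for a motif of Argonaute proteins numbered 0 in WT, 256 in AGO1, 0 in DCR1 and 237 in AGO1DCR1. Reads coding for a motif of Dicer-type RNase III numbered 1, 0, 30 and 26. Among the marker genes, URA3 (uracil synthesis; chromosome V, 116167 to 116970, build R64) had 0 reads in all 4 libraries, which allows up to 2.97 scaled reads in WT. TRP1 (tryptophan synthesis; IV, 461842 to 462516) had 333.2 scaled reads in WT, 8524 in AGO1, 236.5 in DCR1 and 1898 in AGO1DCR1, 25.5-fold higher in AGO1 than in WT and 5.69-fold higher in AGO1DCR1. TRP1 is a common selection marker, and the labels do not say whether a copy came with the AGO1 gene. CAN1, the arginine permease, was 3.23-fold higher in AGO1 and 2.06-fold higher in AGO1DCR1 than in WT. Log2 ratios of AGO1DCR1 to WT were -0.81 for LEU2 (III, 91324 to 92418), -0.43 for MET17, -0.10 for LYS2, -0.04 for HIS3 and 0.49 for ADE2, all under the 2-fold threshold. The list of marker genes had a median of -0.04 (percentile 60.5).

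The comparison of AGO1DCR1 with WT asks what the complete pathway changes. Genes past the threshold included 10 lower of 51 in amino acid biosynthesis, 5 lower of 23 in sulfur metabolism, 7 lower of 40 in the general stress response and 4 higher of 20 in the subtelomeric families. In DCR1 alone, amino acid biosynthesis, sulfur metabolism and the general stress response had 7, 3 and 10 members lower. In AGO1 alone, the subtelomeric families had 6 members higher and 1 lower. LEU1, the isopropylmalate isomerase of leucine synthesis (VII, 476313 to 478652), fell from 21063 scaled reads in WT to 2774, 7.59-fold lower (log2 ratio -2.92, interval -2.98 to -2.87). The mitochondrial carrier gene OAC1 (XI, 217344 to 218318) was 6.84-fold lower and the branched-chain aminotransferase gene BAT1 (VIII, 517532 to 518713) 5.42-fold lower. A similar fall was seen in DCR1 alone, where LEU1, OAC1 and BAT1 had 2760, 750.0 and 3619.5 scaled reads. In AGO1DCR1 they had 2774, 608.3 and 2945.1. FIG2, a cell wall adhesin of mating cells (III, 267434 to 272263), rose from 110.7 to 886.9 scaled reads, 7.98-fold higher (log2 ratio 3.0, interval 2.72 to 3.30), but had 736.0 in AGO1 alone and 109.5 in DCR1.

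Of 5182 genes tested, 199 were higher and 115 lower in AGO1DCR1 than in WT. After FIG2, the largest ratios were those of YPR078C (7.84-fold), YPL038W-A (7.57-fold), PEX9 (7.50-fold), a peroxisomal import receptor gene, the isomaltase gene IMA5 (6.73-fold) and the oxysterol-binding protein gene HES1 (6.57-fold). NFT1 (5.76-fold), PBI1 (5.75-fold), TRP1 (5.69-fold), the urea transporter gene DUR3 (5.19-fold), the flocculin gene FLO10 (5.18-fold) and the dihydroxyacetone kinase gene DAK2 (4.96-fold) followed. Support was thin for some: YPR078C had 13 reads from 7 start positions in WT, YPL038W-A 14 reads from 4 and PEX9 24 reads from 3, and the block sets of PEX9 had log2 ratios of 5.05 and 0.80. The smallest ratio was that of PKP1, a mitochondrial protein kinase gene (IX, 275108 to 276292), at 14.7-fold lower, but it rested on 9 reads from 2 start positions in AGO1DCR1 against 136 reads in WT. YJR115W (6.90-fold lower), YKR075C (6.38-fold), the sulfate permease gene SUL1 (5.89-fold), SOL2 (5.04-fold), the iron-sulfur scaffold gene ISU2 (4.86-fold), the glycogen synthase gene GSY1 (4.77-fold), HPF1 (4.42-fold) and TMA10 (4.05-fold) were the other lowest genes. Of these, YJR115W rested on 18 reads from 4 start positions in AGO1DCR1 and SUL1 on 25 from 5.

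**Figure D1:**
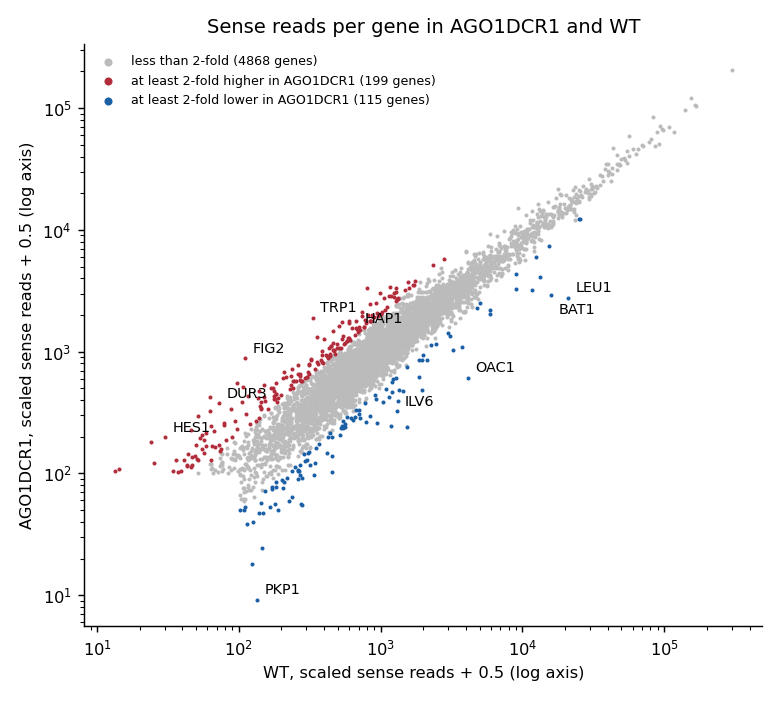
Scaled sense reads per gene (0.5 added, log axes) in WT and AGO1DCR1, with 1 point per gene among the 5182 tested. The 199 genes at least 2-fold higher in AGO1DCR1 are red and the 115 at least 2-fold lower are blue; LEU1, BAT1 and OAC1 lie below the other genes of their expression, and FIG2 and TRP1 above.

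The counts depended on scaling, on the reference and on how reads were counted. With the mean of WT, AGO1 and DCR1 as reference, 32 genes were higher and 82 lower. With each read position counted once, 30 were higher and 25 lower. There the minimum applied to start positions, so fewer genes could be called. POL12, an example chosen after its values were seen, had 290.7 scaled reads in WT and 610.2 in AGO1DCR1. These came from 76 and 50 start positions. The number of genes tested that way is not given, so the drop does not show what share of calls was lost. Scaling by total sense reads moved the median log2 ratio of all tested genes from 0.0 to 0.211 for AGO1DCR1 against WT, from -0.016 to 0.111 for AGO1 against WT and from -0.016 to 0.17 for AGO1DCR1 against DCR1. For AGO1DCR1 against WT it gave 374 genes higher and 63 lower (85.6% higher, against 63.4%). The log2 ratio of AGO1DCR1 to WT correlated across genes with gene length (Spearman 0.48) and with GC content (-0.30), and with the joint trend on length, GC content and expression removed 106 genes were higher and 95 lower. Genes are not independent replicates. Requiring a 2-fold difference in both block sets of a gene left 111 higher and 64 lower. The MAD of the log2 ratios was 0.45 (interval 0.44 to 0.46), against 0.06 for Poisson counting, and ratios from the separate block sets correlated at r = 0.56.

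**Figure D2:**
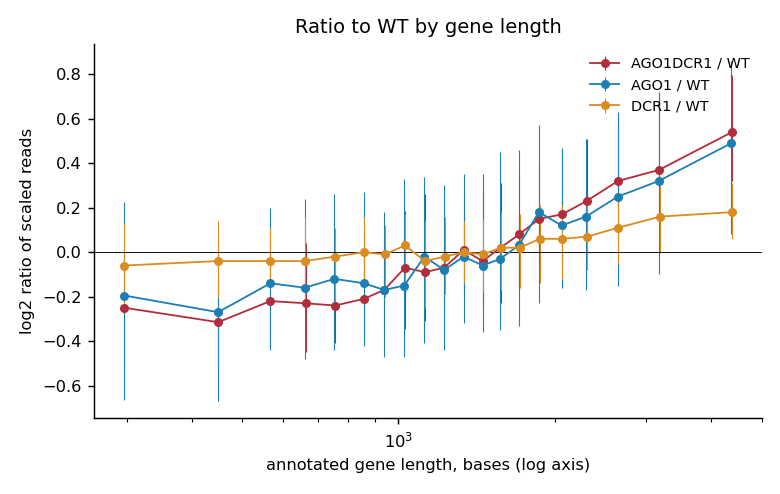
Median log2 ratio to WT (points) and its middle range over genes (vertical lines, lower to upper quartile) in groups of genes ordered by annotated length in bases (log axis), for AGO1DCR1, AGO1 and DCR1. Long genes had higher ratios than short genes, with Spearman correlations of 0.48 for AGO1DCR1, 0.29 for AGO1 and 0.20 for DCR1.

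Among the lists fixed beforehand, 12 of 31 lay in the lowest or highest 1% of matched random lists for AGO1DCR1 against WT. With the mean of WT, AGO1 and DCR1 as reference, 7 did. In amino acid biosynthesis, 10 of 51 members fell and 1 rose, with a median log2 ratio of -0.32 (percentile 0.14). LEU1 and BAT1 led, followed by ILV6 (4.02-fold lower) and ILV3 (3.59-fold lower), which act in isoleucine and valine synthesis. In DCR1 alone, the same list had a median of -0.26 against WT (percentile 0.00, 7 fell). Reads matching the reference across 2 sites of LEU2 were found in DCR1 and AGO1DCR1. These sites were picked for having no such read in WT and AGO1, so the absence there was fixed by the choice. In sulfur metabolism, 5 of 23 members fell, with a median of -0.45 (percentile 0.01). They included SUL1, STR3 (2.29-fold lower), MET28 (2.11-fold lower) and the methionine synthase gene MET6 (2.10-fold lower). DCR1 alone had a median of -0.32 against WT for sulfur metabolism (percentile 0.00, 3 fell). In the general stress response, 7 of 40 members fell and none rose, with a median of -0.33 (percentile 0.00). The leading members GSY1, GAC1 (3.81-fold lower), GLC3 (3.65-fold lower) and HXK1 (3.41-fold lower) act in glycogen synthesis or glucose phosphorylation. DCR1 alone had the same median of -0.33 against WT for the general stress response (percentile 0.00, 10 fell). In the phosphate regulon, 3 of 18 members fell, with a median of -0.36 (percentile 0.47): SPL2 (2.78-fold lower), PHO12 (2.29-fold lower) and PHM7 (2.25-fold lower). VTC1 had a log2 ratio of -0.87. The phosphate regulon had a median against WT of -0.48 in AGO1 alone (percentile 0.15, 3 fell) and -0.09 in DCR1 alone (percentile 4.91). With the trend on length, GC content and expression removed, these 4 lists had percentiles of 0.00 for AGO1DCR1 against WT. Their medians were then -0.18, -0.40, -0.34 and -0.33 in the order given. By total scaling the medians were -0.11 (interval -0.36 to 0.01), -0.24, -0.12 (-0.32 to 0.06) and -0.15 (-0.51 to 0.09). With each read position counted once, amino acid biosynthesis had -0.05 and the phosphate regulon -0.06.

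Of 20 members of the subtelomeric families, 4 rose and none fell, with a median of 0.65 (percentile 99.97). FLO10, the flocculin gene FLO5 (2.89-fold), the mannoprotein gene DAN4 (2.84-fold) and AAD3 (2.60-fold) were the 4. Only 20 of the 57 members had enough reads placed once, and the median was 0.27 with reads of several places shared between them, 0.35 with each read position counted once and 0.17 with the mean of WT, AGO1 and DCR1 as reference. In AGO1 alone, the same list had a median of 0.51 against WT (percentile 95.9; 6 rose and 1 fell). FLO10, FLO5 and AAD3 had 342.1, 369.9 and 745.6 scaled reads there, against 324.9, 158.1 and 396.2 in AGO1DCR1. In the zinc regulon, 1 of 11 members rose, the zinc transporter gene ZRT1 (2.26-fold), and the median was 0.46 (interval -0.36 to 0.98, percentile 99.48). ZAP1 (0.98), ZRT2 (0.90) and ADH4 (0.65) had log2 ratios under the threshold, and the median was 0.25 with each read position counted once and 0.21 with the mean reference. Against WT, the zinc regulon had a median of 0.24 in AGO1 alone (percentile 86.6) and -0.21 in DCR1 alone (0.78). ZRT2 and ADH4 had 2976.5 and 2559.6 scaled reads in AGO1, against 1698.6 and 1904.0 in AGO1DCR1. ZRT1 and ZAP1 had 1442.2 and 385.2 in AGO1, against 2796.7 and 515.8. No cell cycle gene passed the threshold among 30, and the median was 0.31 (percentile 99.78), with SWI4 at 0.99, CLB5 at 0.91 and CDC5 at 0.83. The cell cycle median was 0.05 with each read position counted once and 0.52 by total scaling. Against WT it was 0.15 in AGO1 alone (percentile 87.3) and 0.15 in DCR1 alone (98.85). SWI4, CLB5 and CDC5 had 1372.3, 340.2 and 1044.5 scaled reads in AGO1, against 1231.1, 591.0 and 1045.0 in AGO1DCR1. With the trend removed, these 3 lists had percentiles of 99.87, 100 and 99.97.

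The other 5 lists in the outer 1% held 1 gene past the threshold. Ribosomal protein genes had a median of -0.48 (percentile 0.00; 137 genes), with RPL22B at -0.95, RPL8A at -0.83, RPL42B at -0.81 and RPS24B at -0.74. The unfolded protein response had a median of -0.42 (percentile 0.05), with HAC1 at -0.86, MPD1 at -0.71, FPR2 at -0.62 and SCJ1 at -0.62. Glycolysis and fermentation had a median of -0.56 (percentile 0.01), in which the glucokinase gene GLK1 fell (3.01-fold lower) and ENO2, PDC1 and ADH1 had ratios of -0.88, -0.87 and -0.83. Respiration and the TCA cycle had a median of -0.34 (percentile 0.00), with QCR6 at -0.81, ATP5 at -0.80, COX5A at -0.74 and SDH1 at -0.74. Sterol and lipid synthesis had a median of -0.05, above that of random lists (percentile 99.44), which was 0.16 by total scaling; INO2, CHO1, ERG2 and ERG10 had ratios of -0.75, -0.61, -0.42 and -0.37. Length, GC content and expression together went with most of these, and none of the 3 was separated: with their joint trend removed, the medians were -0.04 for ribosomal proteins (percentile 0.80), -0.08 for glycolysis (10.1), -0.07 for respiration (8.24) and 0.11 for sterol synthesis (96.6), while the unfolded protein response had -0.32 (0.02), and -0.21 by total scaling. With each read position counted once, ribosomal proteins had 0.70, glycolysis 0.64 and respiration 0.02. Abundant genes are saturated by this count: RPL42B had 97 start positions in WT and 94 in AGO1DCR1, and ENO2 had 771 and 765. The values for ribosomal proteins and glycolysis therefore cannot check the medians from reads.

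No other list lay in the outer 1%. Median log2 ratios were -0.07 for ribosome biogenesis (percentile 72.8), -0.10 for heat shock factor chaperones (88.9), 0.01 for purine biosynthesis (80.6) and 0.10 for glucose-repressed carbon use (57.4). Hexose transporters had -0.48 (3.02), the iron regulon 0.03 (53.0), mating type a genes 0.85 over 4 members (98.9) and mating type alpha genes -0.49 over 4 members (1.5). Haploid and pheromone response genes had 0.11 (64.4), meiosis and sporulation 0.19 (79.3), histones -0.31 (11.1) and cell wall genes -0.07 (73.2). RNA decay and surveillance had -0.13 (1.47), viral dsRNA host factors 0.02 (57.5), translation factors -0.16 (87.6) and antisense regulated loci -0.20 (22.6). Oxidative stress had -0.16 (14.7) and multidrug resistance -0.00 (42.0).

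The comparison of AGO1 with WT shows the strain with Argonaute alone. Here 455 of 5222 genes were higher and 186 lower. TRP1 rose 25.5-fold, YPL038W-A 23.4-fold, HES1 12.8-fold, PBI1 12.7-fold and PEX9 11.4-fold. The pheromone gene MF(ALPHA)2 was 25.3-fold lower, the DNA 3' phosphatase gene TPP1 18.8-fold lower, the Mediator subunit gene PGD1 10.6-fold lower, YLR456W 9.53-fold lower and the drug transporter gene QDR2 6.98-fold lower. In AGO1 these 5 lower genes rested on 1 to 9 start positions each (29 reads from 2 positions for MF(ALPHA)2). The MAD was 0.57. Total scaling gave 565 higher and 132 lower (81.1% higher, against 71.0%), and with the trend removed 300 were higher and 210 lower. Requiring a 2-fold difference in both block sets left 248 higher and 97 lower. With each read position counted once, 297 genes differed in either direction, but fewer genes reached the minimum in that count. The AGO1 library had 468039 distinct start positions, against 1344254 in WT. Log2 ratios of the 2 block sets differed with a MAD of 0.62, against 0.11 for Poisson counting.

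The comparison of DCR1 with WT shows the strain with Dicer alone. Only 15 of 5138 genes were higher and 64 lower, and the MAD was 0.25. LEU1 was 7.63-fold lower (log2 ratio -2.93, interval -2.99 to -2.87), OAC1 5.55-fold lower, the hexose transporter gene HXT7 4.59-fold lower, BAT1 4.41-fold lower and REG2 4.35-fold lower. The ER-phagy receptor gene ATG40 was 3.14-fold higher, FRT2 2.81-fold, YHR175W-A 2.80-fold, SOA1 2.77-fold and MRX7 2.38-fold, although 1 block set of ATG40 (0.89) and of YHR175W-A (0.55) had a log2 ratio below 1. Requiring the difference in both block sets left 4 higher and 39 lower.

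**Figure D3:**
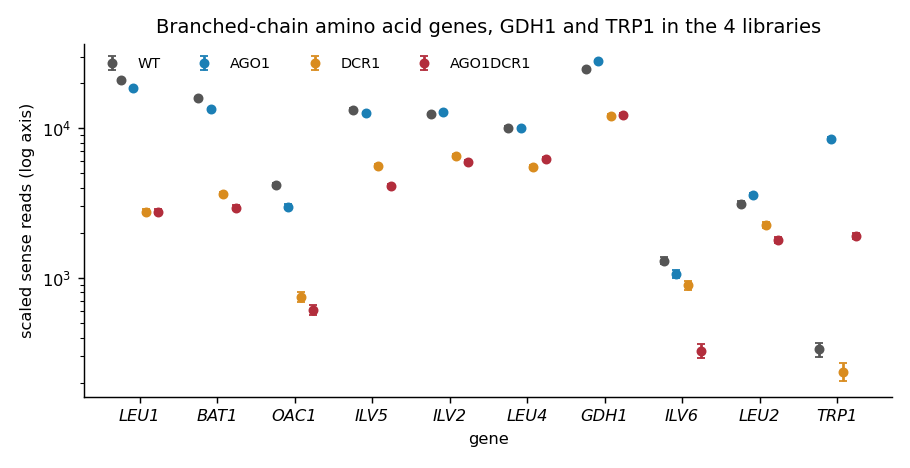
Scaled sense reads (log axis) of 7 target genes of the regulator Leu3, of ILV6, LEU2 and TRP1 in the 4 libraries; lines are 95% counting intervals, mostly within the points. LEU1, BAT1 and OAC1 were lower in DCR1 and AGO1DCR1 than in WT and AGO1, and TRP1 was higher in AGO1 and AGO1DCR1; the genes shown were chosen after some of their values were seen.

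Adding Dicer to Argonaute (AGO1DCR1 against AGO1) gave 175 of 5221 genes higher and 245 lower, or 223 and 208 by total scaling (51.7% higher, against 41.7%). HLR1, which had 0 reads in AGO1, was at least 40.2-fold higher over the limit of 3 reads. TPP1 (28.0-fold), YPR078C (14.6-fold), YLR456W (13.5-fold) and MF(ALPHA)2 (10.1-fold) were also higher. In AGO1 these rested on 7 reads from 1 start position, 7 from 1, 12 from 2 and 29 from 2. HLR1, TPP1, YPR078C, YLR456W and MF(ALPHA)2 had 42.5, 134.5, 12.9, 113.7 and 714.8 scaled reads in WT. In AGO1DCR1 they had 115.7, 200.5, 104.1, 161.0 and 285.4. XYL2 was 14.2-fold lower, YMR158C-A 9.51-fold, CSM2 8.88-fold, DIT2 8.68-fold and ULI1 8.23-fold lower; for CSM2 the block sets had log2 ratios of 5.22 and -4.37. Ratios from the separate block sets correlated at only r = 0.24. Requiring a 2-fold difference in both block sets left 81 higher and 101 lower. With each read position counted once, 38 genes differed in either direction, again with fewer genes reaching the minimum.

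Adding Argonaute to Dicer (AGO1DCR1 against DCR1) gave 173 of 5165 genes higher and 51 lower, or 305 and 29 by total scaling (91.3% higher, against 77.2%). YNL195C, with 3 reads in DCR1, had a ratio of 27.3 (log2 interval 3.40 to 7.29). FLO5 (9.99-fold), YKR104W (9.44-fold), PRM9 (8.67-fold) and FIG2 (8.07-fold) were also higher. PKP1 was 11.9-fold lower, CIS1 6.44-fold, MRPL4 3.93-fold, SOL2 3.35-fold and HPF1 3.23-fold lower. The correlation with gene length was 0.42, and with the trend removed 96 were higher and 58 lower. Requiring a 2-fold difference in both block sets left 77 higher and 20 lower. With each read position counted once, 22 genes differed in either direction, again with fewer genes reaching the minimum.

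Many calls were shared between strains. Of the genes higher than WT in AGO1DCR1, 144 were also higher in AGO1 (15.2 if independent), and 28 were lower in both (4.1 if independent). AGO1DCR1 and DCR1 shared 7 higher genes (0.4 if independent) and 31 lower genes (1.4 if independent), and AGO1 and DCR1 shared 6 higher (0.7) and 9 lower (2.3). All of these ratios use the same WT library, and a low value there alone would raise DCR1 against WT as well. Over the 144 genes, the median log2 ratio of DCR1 to WT was 0.27 (interval 0.19 to 0.33), with 5 called higher. Over the 28 genes it was -0.52 (-0.85 to -0.31), with 6 called lower. For the 7 and 31 genes shared with DCR1, AGO1 had medians to WT of 1.86 and -0.41. For the 6 and 9 genes shared by AGO1 and DCR1, AGO1DCR1 had 1.85 and -1.35. Across 5144 genes, the log2 ratios of AGO1 and DCR1 to WT correlated at r = 0.15 (interval 0.11 to 0.19; Spearman 0.14), with a covariance of 0.034. In simulated counts without any change, the shared WT library alone gave r = 0.51, a covariance of 0.0034 and 0 shared calls. That simulation leaves out the spread between libraries, so it decides neither value.

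Genes that set AGO1DCR1 apart from all 3 other libraries were few. Of 5252 genes, 45 were at least 1.5-fold above and 80 at least 1.5-fold below the nearest other library. The same count was 37 above and 69 below for WT, 357 and 310 for AGO1, and 17 and 72 for DCR1. Above the others lay YPR078C (3.61-fold to the nearest library), YJL077W-B (2.80-fold), SPS4 (2.35-fold), SUE1 (2.35-fold), ECM2 (2.31-fold), HAP1, a haem-responsive activator (2.09-fold; XII, 646415 to 650923), THI73 (2.08-fold) and CSI1 (2.01-fold). Below lay PKP1 (6.64-fold), SOL2 (3.35-fold), CSM2 (2.98-fold), ILV6, the regulatory subunit of acetolactate synthase (2.77-fold; III, 104619 to 105548), XYL2 (2.69-fold), HPF1 (2.56-fold), SUL1 (2.56-fold) and YJR115W (2.55-fold). Support was thin for some of these genes. In AGO1DCR1, XYL2 rested on 9 reads from 3 start positions, YJR115W on 18 from 4 and SUL1 on 25 from 5. YJL077W-B had 1 start position in DCR1, and SPS4 had 3 in AGO1. Without the AGO1 library, 544 genes lay 1.5-fold beyond both remaining libraries. The log2 difference between AGO1DCR1 and the sum of the single-protein ratios was above 1 for 116 of 4930 genes and below -1 for 138, with a MAD of 0.47 against 0.08 for Poisson counting. With each read position counted once, 9 genes were beyond 1 in either direction, and 13 set AGO1DCR1 apart by 1.5-fold. Fewer genes reached the minimum in that count, so these numbers are not out of the 4930 and 5252 genes above.

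Among the Ty retrotransposons, Ty1 and Ty2 sense RNA was lower in AGO1DCR1 than in WT, while Ty3 and Ty4 had ratios above 1. Ty1 sense RNA (31 annotated copies) fell from 54445 scaled reads in WT to 18352 in AGO1DCR1, 2.97-fold lower (log2 ratio -1.57, interval -1.59 to -1.55). It was 4.03-fold lower than in AGO1 and 3.68-fold lower than in DCR1, where Ty1 had log2 ratios to WT of 0.44 and 0.31. Ty2 sense RNA (13 copies) was 2.06-fold lower than in WT, 3.01-fold lower than in AGO1 and 1.73-fold lower than in DCR1. Reads shared by several families were 4.69-fold lower than in WT. Ty3 (2 copies) and Ty4 (3 copies) had log2 ratios of AGO1DCR1 to WT of 0.95 (0.82 to 1.08) and 0.96 (0.85 to 1.08), and 1.45 and 1.02 for AGO1 to WT. By total scaling, Ty2 had -0.83, Ty3 1.16 and Ty4 1.17, and with the mean of WT, AGO1 and DCR1 as reference Ty3 had 0.24 and Ty4 0.53. Ty5 had 0 reads in all libraries. The annotated Ty genes had a median of -1.06 over 16 genes (percentile 0.00), against 0.79 for AGO1 and 0.19 for DCR1.

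Log2 ratios of Ty antisense reads in AGO1DCR1 to WT were -0.29 for Ty1, -0.20 for Ty2 and 1.42 for Ty3. The value for Ty2 was 0.01 by total scaling and 1.89 with only Ty reads placed once, where Ty2 sense reads had -1.38 and Ty1 antisense reads -0.01. With the mean of WT, AGO1 and DCR1 as reference, antisense ratios were -0.81 for Ty1, -0.80 for Ty2 and 0.24 for Ty3. AGO1 had more antisense reads than WT, with ratios of 1.16 for Ty1, 1.28 for Ty2 and 2.15 for Ty3. Ty4 antisense reads numbered 0 in WT, 80 in AGO1, 12 in DCR1 and 8 in AGO1DCR1.

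**Figure D4:**
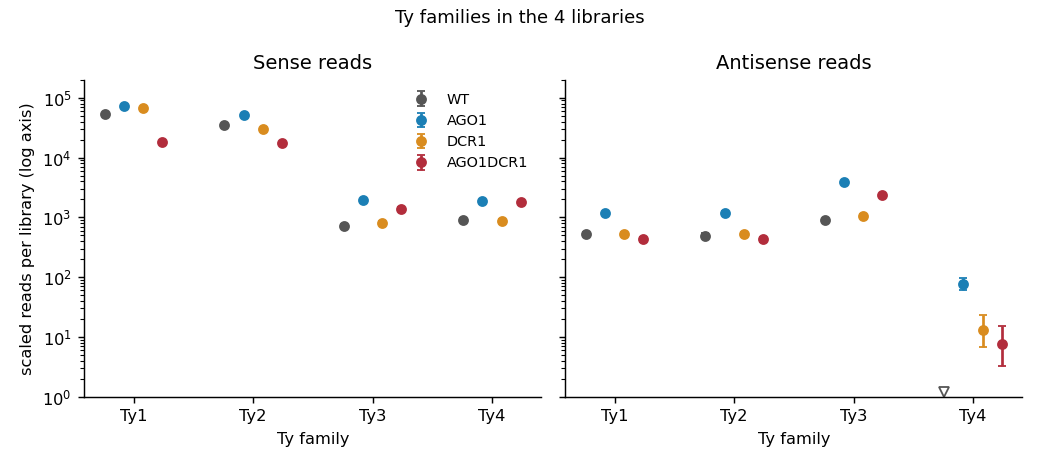
Scaled sense reads (left) and antisense reads (right) per Ty family and library (log axes); lines are 95% counting intervals, mostly within the points, and the open triangle marks 0 reads. Ty1 and Ty2 sense reads were lowest in AGO1DCR1, with log2 ratios to WT of -1.57 and -1.04.

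Antisense RNA over genes can pair with mRNA into the substrate of Dicer. Its share of gene reads was 0.662% in WT, 1.29% in AGO1, 0.720% in DCR1 and 1.07% in AGO1DCR1 (exact binomial intervals 0.657 to 0.666, 1.28 to 1.30, 0.715 to 0.725 and 1.06 to 1.08). Over 1707 genes chosen for their antisense reads in AGO1 and DCR1, a choice that favours these libraries, the median log2 ratio to WT was 0.35 (interval 0.26 to 0.45) in AGO1DCR1, 1.28 in AGO1 and 0.29 in DCR1. Over the same genes, AGO1DCR1 had a median of -0.76 against AGO1 and 0.11 against DCR1, and how far that choice lowered these values was not tested. The 530 genes with most antisense had a median sense ratio of 0.16 (percentile 100) in AGO1DCR1 against WT, which became -0.05 (percentile 4.30) with the trend on length, GC content and expression removed and -0.02 with each read position counted once. The 1981 convergent genes had a median of -0.00 (interval -0.02 to 0.02, percentile 2.49), which was 0.21 by total scaling.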

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

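The searches for proteins absent from R64 were run outside the comparisons of genes, and each value here was picked out because reads appeared above the level in WT or above the limit that a count of 0 allows. All of these searches were chosen after the libraries were seen. Reversed proteins, used as a control, matched 1 read over all libraries and proteins.

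Sense reads of the K1 killer virus preprotoxin reached 20760 in AGO1, against 19524 in WT. Antisense reads of the Gag protein of the L-A virus numbered 31 in AGO1DCR1, from 4 positions, against 9 in WT. Antisense reads of the kanamycin resistance protein KanR numbered 55 in AGO1, from 2 positions, against 1 in WT. Sense reads of GFP numbered 2278 in DCR1, against 2161 in WT.

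Reads of the TEM beta-lactamase of bacterial plasmids were almost absent from WT and present in the other libraries. Sense reads numbered 8 in WT, 534 in AGO1, 95 in DCR1 and 213 in AGO1DCR1. Antisense reads numbered 0 in WT, 6268 in AGO1, 1041 in DCR1 and 2013 in AGO1DCR1. Over the limit of 3 reads in WT, antisense reads were at least 2025-fold higher in AGO1, at least 384-fold higher in DCR1 and at least 654-fold higher in AGO1DCR1.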

How the results depend on the processing

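Of 155 alternative values of results that answer a comparison, 92 were labelled the same as the reported value, 61 moved and 2 reversed. Of 148 others, 103 were labelled the same, 38 moved and 7 reversed. These cover 18 planned settings and 3 chosen after seeing the data (trend removal, both block sets, AGO1 left out). A value labelled the same need not be close. That label includes 199 genes higher becoming 296 with no minimum. It also includes a subtelomeric median of 0.65 becoming 0.17 with the mean reference. Ty1 was labelled moved when it went from -1.57 to -1.54 with TMM scaling. Where no reason is given, the cause was not tested. Here, higher and lower are counts for AGO1DCR1 against WT, and other comparisons have 1 total.

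With scaling by total reads, 374 genes were higher and 63 lower, and log2 ratios of AGO1DCR1 to WT were 0.37 for genes with most antisense, 0.56 for antisense reads, 0.21 for convergent genes and -1.36 for Ty1, while Ty2 antisense reversed to 0.011. These follow a shift of all genes. With TMM scaling, convergent genes had 0.024 and Ty1 -1.54.

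Minimums and thresholds change counts by construction. With a minimum of 20 scaled reads, 175 genes were lower, 193 differed in DCR1 against WT and 363 in AGO1DCR1 against DCR1, 218 were set apart and 444 non-additive. With no minimum these were 208, 250, 441, 257 and 756, with 645 for AGO1DCR1 against AGO1. With a minimum of 500, 127 were higher and 63 lower, 399 differed in AGO1 against WT, 29 in DCR1 against WT, 189 in AGO1DCR1 against AGO1 and 93 against DCR1, 52 were set apart and 50 non-additive. With a 1.5-fold threshold, 648 were higher and 398 lower, and totals were 1637 for AGO1 against WT, 356 for DCR1 against WT, 1286 for AGO1DCR1 against AGO1 and 859 against DCR1. With 2-fold, 26 were set apart.

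With each read position counted once, abundant genes are saturated and fewer genes reach the minimum, which lowers the counts by construction. That count gave 30 higher and 25 lower. Totals were 297 (AGO1 against WT), 12 (DCR1 against WT), 38 (AGO1DCR1 against AGO1) and 22 (against DCR1). There 13 were set apart and 9 non-additive, the spread was 0.32 and the correlation 0.10. Genes with most antisense reversed to -0.019, ribosomal proteins to 0.70, glycolysis to 0.64 and respiration to 0.019.

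With Ty reads placed once, Ty1 had -1.39; Ty2 antisense reversed to 1.89 and Ty4 antisense, with 0 such reads in both libraries, to -0.036. Overlapping convergent genes had 0.10 and those within 100 bp 0.052. With the mean of WT, AGO1 and DCR1 as reference, 32 were higher and 82 lower, the spread was 0.34, 7 lists lay in the outer 1%, genes with most antisense had 0.064 and Ty1 -1.83, and Ty4 antisense reversed to -1.93.

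With the trend removed, 106 were higher, the spread was 0.34 and genes with most antisense reversed to -0.051. With both block sets required, which adds a condition, 111 were higher and 64 lower, and totals were 345, 43, 182 and 97 for AGO1 and DCR1 against WT and AGO1DCR1 against AGO1 and DCR1. Without AGO1, with fewer libraries to exceed, 544 were set apart. Depth limits genes under 100 scaled reads and, in AGO1, genes with few start positions.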

Other observations

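For Ty1, the tests of a variant along the whole element and of the share of copies that fell were written before their results were seen, that of 2 to 4 mismatches after the other Ty1 values; the tests of 2 parts of the element and of copies still present, all other tests here, and the list of Leu3 target genes, were chosen after.

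Several fixed lists moved in the strains with 1 protein. For AGO1 against WT, 5 lists lay in the outer 1% of matched random lists. Heat shock factor chaperones had a median log2 ratio of 0.29 (percentile 100; 2 of 24 rose) and the iron regulon 0.47 (99.63; 7 of 26 rose and 2 fell). Glycolysis and fermentation had -0.65 (0.00), the phosphate regulon -0.48 (0.15; 3 of 18 fell) and histones -0.56 (0.04), which was -0.12 (26.7) with the trend on length, GC content and expression removed. For DCR1 against WT, 11 lists did, among them the general stress response with a median of -0.33 (0.00; 10 of 40 fell), amino acid biosynthesis -0.26 (0.00; 7 of 51 fell), sulfur metabolism -0.32 (0.00; 3 of 23 fell) and ribosome biogenesis 0.14 (100; no gene past the threshold).

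Sense reads of GFP and KanR were found in every library. KanR numbered 34584 in WT, 22571 in AGO1, 30956 in DCR1 and 24810 in AGO1DCR1, and GFP 2161, 1151, 2278 and 1756. Sense reads of L-A Gag numbered 33, 17, 32 and 35. No read matched the hygromycin or nourseothricin resistance proteins.

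Ty1 sense RNA was 2.97-fold lower in AGO1DCR1 than in WT, unevenly along the element, from a log2 ratio of -0.36 in the fifth of 10 equal parts to -3.66 in the last. A variant with 1 to 4 differences from R64 in a read as the cause along the whole element is argued against by the reads with 1 mismatch (-1.48) and with 2 to 4 (-1.21, interval -1.24 to -1.19), but stays open in parts 3 and 4, where reads with 2 to 4 had -0.23 (-0.29 and -0.16), as does one with more differences. The 6 copies with at least 20 reads of their own in AGO1DCR1 had a sum of -1.19, from -2.08 for YBLWTy1-1 to -0.14 for YOLWTy1-1. YNLWTy1-2 and YMRCTy1-3 gave 746 and 345 of their 1592 reads in WT. The sum argues against loss of copies as the whole cause only if reads unique in R64 come from 1 copy in these strains. That was not tested. Loss of single copies stays open: of 13 copies (31 annotated) with 20 own reads in WT and AGO1DCR1 together, 84.6% were below -0.5 (interval 54.6 to 98.1). YMLWTy1-2 had 231 reads in WT and 2 in AGO1DCR1. Loss of reads with several places as the whole cause is argued against by Ty1 reads placed once, with a log2 ratio of -1.39 (interval -1.51 to -1.27). Ty3, the lower of Ty3 and Ty4, had a log2 ratio of 0.95. Both rose more in reads placed once (1.18 and 1.65) than in all reads (0.95 and 0.96), so they cannot exclude a partial loss of such reads. Joint action of both proteins remains open as a hypothesis, since Ty1 was lower in AGO1DCR1 than in either single-protein strain (-1.88 against the nearer), but with 1 strain each an unrelated difference between strains may give the same values.

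K1 preprotoxin sense reads numbered 2695 in AGO1DCR1, 7.43-fold lower than in WT, and the antisense reads numbered 88 in WT, 28 in AGO1, 36 in DCR1 and 0 in AGO1DCR1. A lower yield of all transcripts from outside R64 is argued against by KanR, the lower of KanR and GFP, at a log2 ratio of -0.52. Neither is a viral RNA, so they cannot tell whether viral RNA was captured less well in that library. L-A Gag, also viral, had only 33 sense reads in WT and 35 in AGO1DCR1. A virus variant that differs in part of the sequence is argued against by the least changed of 3 equal parts of the protein, at -2.82. A candidate explanation is that both proteins together lower this viral RNA, since reads were also lower than in the nearer single-protein strain (-2.74). Partial loss of the virus by chance in that strain could give the same values and was not tested.

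The Leu3 target genes LEU1, LEU4, ILV2, ILV5, BAT1, OAC1 and GDH1 had a median log2 ratio of -1.24 in DCR1 against WT (7 genes, -2.93 to -0.87) and -0.08 in AGO1 against WT. This pattern was itself seen in a strain without AGO1, so that the value of -1.24 only restates that both proteins were not needed for it. An intact LEU2 copy, which may come with DCR1, remains open. In the libraries with DCR1, 39 reads matched R64 exactly across LEU2 sites at III 91563 to 91576 and 92105 to 92120. They numbered 13 and 3 in DCR1 and 10 and 13 in AGO1DCR1. The sites were picked because the libraries without DCR1 had 0 such reads there, so that 0 is no support. Reads with a 1-base insertion or deletion at these sites numbered 25 and 46 in WT and 95 and 63 in AGO1, against 6 and 4 in DCR1 and 4 and 7 in AGO1DCR1, while at 2 LEU2 sites with no exact read in the libraries with DCR1 the other libraries had at most 1. The median of -1.61 in AGO1DCR1 against AGO1 would follow from Dicer itself as well, and Dicer and a LEU2 copy cannot be told apart because any such copy lies in the same strains.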
